A study of Mus musculus with 24 samples.

How the data were processed

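Total RNA of the frontal cortex and cerebellum of 12 naive SJL/JOrlCrl mice, 6 of each sex, was amplified, labelled and hybridised to 24 Illumina MouseWG-6 v2.0 arrays, per the labels. Samples were grouped by sex and tissue as their labels give them, with 6 arrays per group. Both tissues of an animal carry the same animal label, so the replicate number within a sex pairs the tissues. This pairing was checked on deviations from the group means. There the correlation of an animal's 2 arrays ran from -0.30 to 0.24 and exceeded 0.1 in 5 of 12 pairs. The consensus correlation of an animal's arrays was -0.016. No animal had both arrays in the same run of 6 neighbouring scanner columns. Deviations of arrays in different runs correlated at a mean of -0.11. With the run removed, the correlations of the pairs ran from 0.02 to 0.33, with 5 pairs over 0.1. The pairing was kept because it comes from the labels, but the main fit held no term for the animal. It entered the average over tissues and the alternatives with the animal as a block.

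The deposited scanner table held, per the file headers, the mean bead intensity of each probe on a linear scale without normalization between arrays, the standard error of that intensity, another value giving the number of beads, and a detection p-value. The detection p-value moved in steps that imply 936 negative controls. The deposited table of the authors held intensity values on a linear scale whose sorted columns were the same to within 0.469%, so they had been quantile-normalized, and their order within an array was that of the scanner signal. Per the submitters' processing notes Partek was used, with neither role nor version given. Values on a log2 scale were computed here from the deposited intensity.

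Median signal ran from 69.3 to 75.2 per array, detected probes from 18099 to 19927 (40% to 44%), mean beads per probe from 44.1 to 45.6, and the median standard error over beads from 4% to 5.14% of the signal. Scanner values were background-corrected and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, which infers the negative controls from the detection p-values, with an offset of 16, and were analysed as log2 intensity. Files were read with the package data.table, version 1.17.8, and array correlations used statmod 1.5.0. Probes with a detection p under 0.05 on at least 6 arrays were kept, which left 21113 of 45281. Of the kept probes 17921 had 1 gene symbol, 8 had several and 3184 had none here. Symbols were updated through the Entrez ID in a RefSeq table of assembly GRCm38.p6, which matched 34807 of the 34885 probes with 1 symbol, and chromosomes were taken from the same table. No coordinates were used.

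A mean per group was fitted to all 24 arrays with lmFit, moderated with eBayes (20 residual and 5.82 prior degrees of freedom), and contrasts were tested for change in either direction with Benjamini-Hochberg adjustment across probes at a threshold of 0.05. All adjusted p for probes come from limma. Contrasts were female minus male in each tissue, the difference between these, and cerebellum minus frontal cortex in each sex. The sex difference averaged over tissues used the mean of each animal's 2 arrays. Probes set apart by the female cerebellum had to be higher there past the threshold in 3 contrasts. Gene lists, 32 in number and fixed before the data were examined, were tested with camera in limma at a preset correlation of 0.01, with 1 probe per gene and adjustment across lists. They were repeated with an estimated correlation and with fry, whose directional p tests whether the members move one way on balance. A fold printed against a group in which a probe was detected on 3 or fewer of 6 arrays is given as a lower bound from the dimmest detected level of each array, and log2 differences are fitted values.

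Genes were named by a rule fixed before the data were examined. It named every gene past the threshold of a sex contrast or the interaction where 30 or fewer passed, otherwise the 12 highest and the 12 lowest, the 10 most raised and the 10 most reduced genes by tissue in females with the same sign in males, up to 10 genes highest in female cerebellum, and always Xist, the Y-linked genes and the S1P receptors where kept. It also named up to 4 members of each list described. A gene was represented by its brightest kept probe. Genes past the threshold of a sex contrast, the interaction or the average by a dimmer probe alone were named as such, which was added after the values were seen. Genes named outside this rule are marked as chosen after their values were seen.

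Alternatives fixed before the data were examined were no background correction, normexp by maximum likelihood with an offset of 50, median scaling, cyclic loess, the authors' values, other filters on dim probes, eBayes with trend and robust settings, array weights, the label batch as a block or each label batch alone, the animal or replicate number as a block, the arrays of a single tissue, a minimum of 1.5-fold, and each array left out in turn. Added after the data were seen were the run of 6 neighbouring scanner columns, taken here as a possible slide, as a block and alone, and the omission of 2 cerebellum arrays with forebrain transcripts. The slide itself is not given by the files. Each run held arrays of all 4 groups.

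The pipeline was tested on simulated data built on the kept probes. Of 200 probes shifted by 0.5 on the log2 scale, 62.5% were recovered by sex in cerebellum, 69.5% in frontal cortex, 25.5% for the interaction, 69% and 66% by tissue in females and males, and 84% for the average over tissues. Of those shifted by 1, 94% to 99% were recovered in these comparisons, with 6 to 17 false calls. At 0.25, recovery was 3.5% or lower. Camera recovered 12 of 12 shifted lists in each of the 5 list comparisons, with at most 1 false call. The simulated probes varied independently, so this does not show the rate of false calls where members of a list are correlated.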

Results

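The series measured transcript levels in the frontal cortex and cerebellum of untreated SJL/JOrlCrl mice of both sexes at 10 weeks of age, on Illumina MouseWG-6 v2.0 bead arrays. SJL mice are an inbred strain widely used to study autoimmune inflammation of the brain, in which females are often the more affected sex. The 24 arrays formed 4 groups of 6, and both tissues came from each of 12 animals. The median signal of an array lay between 69.3 and 75.2 intensity units, and 18099 to 19927 of the 45281 probes were detected per array. Of the probes, 34885 carried 1 gene symbol, 18 carried several and 10378 carried none here. A total of 21113 probes was kept, standing for 11439 named genes. Arrays of the same group correlated at 0.9827 to 0.9954 across kept probes, and arrays of different tissues at no more than 0.9343. The labels split each group into 2 arrays of label batch a and 4 arrays of label batch b, 2 sets marked by different tags whose meaning is not stated. The number of arrays limits the precision of every value below.

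The comparison of the sexes in the cerebellum addressed the stated aim of the series, the transcripts of the female cerebellum. Xist, the RNA that silences an X chromosome, was at least 8.61-fold higher in female cerebellum, as it was detected on 1 of 6 male arrays (fitted log2 difference 3.29 ± 0.14 SE, n = 6 and 6, limma adjusted p = 6.7e-15). S1pr2, which encodes a receptor for the lipid mediator sphingosine-1-phosphate and lies on chromosome 9, was 1.44-fold higher in females (0.53 ± 0.10 SE, adjusted p = 0.023). Its mean log2 level was 7.89 ± 0.17 (SD) in female and 7.37 ± 0.19 in male cerebellum, and 6 of 6 female arrays lay above the male mean. Prl2c3 and Prl2c2, members of the proliferin family of prolactin-like hormones, were 1.68-fold and at least 1.54-fold higher (fitted 0.75 ± 0.10 and 0.72 ± 0.10 SE, adjusted p = 0.00011 and 5.8e-05), with each female array above every male array. A dimmer kept probe of Prl2c2 did not differ (0.03, adjusted p = 1). In the opposite direction, Gm20815 and Gm20867, Y-linked genes that exist in many copies, were detected on each of the 6 male cerebellum arrays and on 0 of 6 female arrays, at least 2.46-fold and 3.29-fold lower in females (adjusted p = 9.2e-11 and 4.4e-13).

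In total 33 probes differed between the sexes in the cerebellum, 11 higher and 22 lower in females. They comprised 14 named genes and 16 probes without a gene name here, which were all lower in females. Of the genes 13 passed by their brightest probe, and Igf2bp3 passed by a dimmer probe alone (-0.55, adjusted p = 0.027, against -0.08 and adjusted p = 1 for the brightest). Further genes higher in females were the X-linked Kif4, a mitotic motor (0.48), Eif2s3x, a translation factor subunit that escapes X inactivation (0.41), and Pbdc1 (0.39), together with Prl2c4 (0.43). Genes lower in females were Cd96, a receptor of lymphocytes (-0.45), Bmp8a, a secreted growth factor (-0.50), and the Y-linked Gm20738 (-1.21). Some of these were dim. Kif4 was detected on 1 of 6 male arrays, and Cd96, Bmp8a and Gm20738 on 2, 3 and 1 of 6 female arrays. As lower bounds their log2 differences were 0.29, 0.35, 0.46 and 0.97 in size. Eif2s3y, the Y-linked partner of Eif2s3x, did not pass (-0.38, adjusted p = 0.44), and neither did Uty (0.01, adjusted p = 1). Uty was detected on 2 of 6 male and 3 of 6 female cerebellum arrays, and Eif2s3y on 5 of 6 and 2 of 6. The mean log2 level of Uty was 4.67, where the dimmest detected level of an array ran from 4.67 to 4.81, so its probe gave no usable check of sex. Xist, Prl2c2, Prl2c3, Eif2s3x, Cd96, Bmp8a and the Y-linked genes stayed past the threshold with any 1 array left out. By contrast Kif4 lost its call in 7, Pbdc1 in 6, Prl2c4 in 17 and the dimmer probe of Igf2bp3 in 9 of these 24 fits. The count of 33 ranged from 26 to 38 over them, and was 34 with the label batch as a block, but 16 in label batch a alone and 149 in label batch b alone.

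The S1pr2 difference depended on the arrays included. Within label batch a it was 0.13 (95% interval -0.19 to 0.45), and within label batch b it was 0.73 (0.50 to 0.95). The adjusted p rose above the threshold without male cerebellum replicate 3 (0.072), 4 (0.059) or 5 (0.092), and without female cerebellum replicate 3 (0.088), 4 (0.062), 5 (0.073) or 6 (0.059), while the log2 difference stayed between 0.48 and 0.59. It was 0.51 with adjusted p = 0.025 when neighbouring runs of 6 array columns were a block, and 0.53 with adjusted p = 0.074 in a fit to the cerebellum arrays alone. Of the other probes of S1pr2, 1 was detected on 0 arrays and 1 on 3 of 24. S1pr5, the other receptor of the family kept here, did not differ detectably in the cerebellum (0.04, adjusted p = 1), and S1pr1, S1pr3 and S1pr4 were too dim to be kept.

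**Figure D1:**
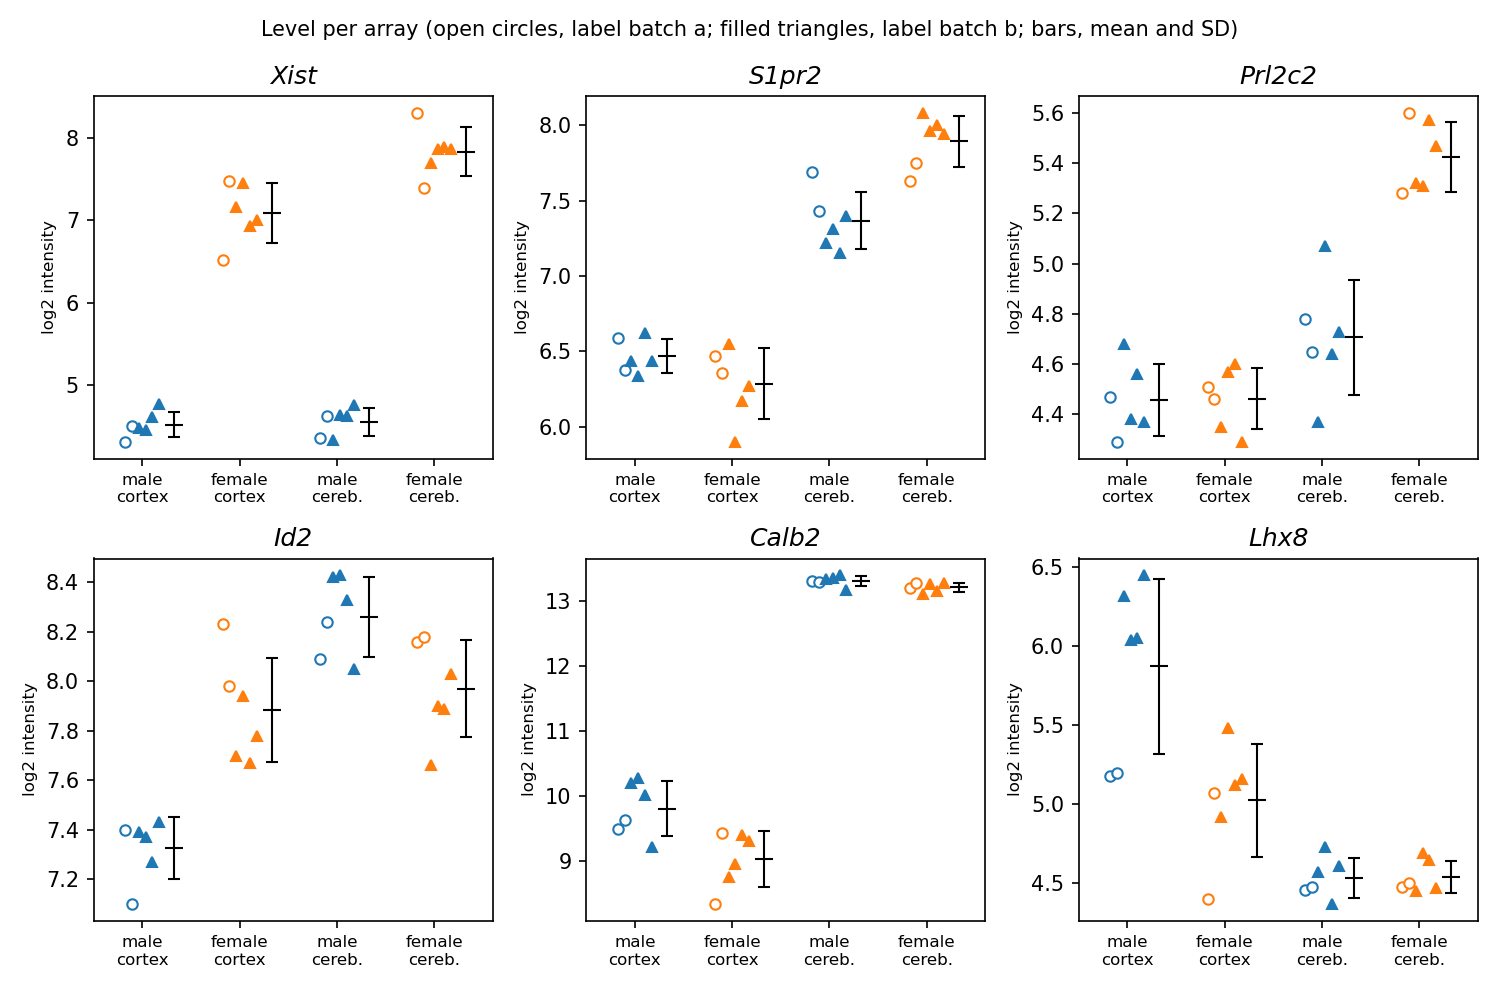
Level of 6 genes on each of the 24 arrays, in log2 intensity on the vertical axis, by group on the horizontal axis. Open circles are label batch a, filled triangles are label batch b, and bars give the mean and SD of 6 arrays. S1pr2 averaged 7.89 in female and 7.37 in male cerebellum, and Lhx8 averaged 5.87 in male and 5.02 in female frontal cortex.

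Among gene lists fixed before the data were examined, X-linked genes known to escape inactivation were higher in female cerebellum (8 measured, 3 higher, 0 lower and 5 not past the threshold, 5 higher when adjusted over the list alone, median 0.34, camera adjusted p = 7.2e-12). This call held with an estimated correlation (adjusted p = 8.2e-06). Xist, Eif2s3x and Pbdc1 were its members past the threshold. For 6 more lists the call did not hold with an estimated correlation. Choroid plexus markers (11 measured, median 0.55, adjusted p = 1.8e-05, and adjusted p = 0.42 with an estimated correlation) and hemoglobin and red cell genes (5 measured, median 0.62, adjusted p = 4.2e-05, and adjusted p = 0.23 with an estimated correlation) shifted higher in females with 0 members past the threshold, and 3 red cell genes passed when adjusted over the list alone. The choroid plexus markers also followed the label batch, a comparison chosen after the data were seen, being lower in batch b by a median of 1.92 in female cerebellum (adjusted p = 7.4e-29, and adjusted p = 0.0027 with an estimated correlation) and by 0.98 in male cerebellum (4e-08 and 0.25). Their mean log2 level was highest on the 2 female arrays of batch a, female cerebellum replicates 1 (7.547) and 2 (8.224). Myelin and oligodendrocyte genes also shifted higher (median 0.12, adjusted p = 0.0023, and adjusted p = 0.56 with an estimated correlation). Their median sex difference was -0.06 within batch a and 0.24 within batch b. Heat shock genes (median -0.11, adjusted p = 0.0023, and adjusted p = 0.19 with an estimated correlation), complement genes (-0.16, adjusted p = 0.013, and adjusted p = 0.45 with an estimated correlation) and glucocorticoid response genes (-0.06, adjusted p = 0.042, and adjusted p = 0.62 with an estimated correlation) shifted lower. Both of the last 2 lists were higher in label batch b of male cerebellum, complement genes by 0.36 (adjusted p = 0.015, and 0.62 with an estimated correlation) and glucocorticoid response genes by 0.55 (6.3e-10 and 0.0043), and not detectably in female cerebellum (0.06 and -0.05, adjusted p = 0.75 for each). Their median sex differences were -0.07 and 0.20 within batch a and -0.25 and -0.23 within batch b. Of the sphingosine-1-phosphate receptor and metabolism genes 17 were measured, of which S1pr2 alone was higher and 16 did not pass, or 2 when adjusted over the list alone (median 0.03, camera adjusted p = 0.30). Without female cerebellum replicate 2 the number of lists past the threshold fell from 7 to 4.

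The comparison of the sexes in frontal cortex asked whether the forebrain differs in the same genes. Xist was at least 5.00-fold higher in females (fitted 2.57 ± 0.14 SE, n = 6 and 6, adjusted p = 5.3e-12) and Eif2s3x 1.39-fold higher (0.48 ± 0.07, adjusted p = 0.001). Id2, an inhibitor of neuronal differentiation factors, was 1.47-fold higher (0.56 ± 0.10, adjusted p = 0.015) and Tnnc1, a troponin subunit, was 1.60-fold higher (0.68 ± 0.13, adjusted p = 0.027), each with all 6 female arrays above every male array. A second probe of Id2, detected on all 24 arrays, did not differ (0.05, adjusted p = 0.99). Cd6, a lymphocyte receptor, was 1.46-fold higher (0.54 ± 0.09, adjusted p = 0.007). In the opposite direction, Igsf1 was 2.49-fold lower in females (-1.31 ± 0.28, adjusted p = 0.041), the forebrain cholinergic transcription factor Lhx8 was 1.80-fold lower (-0.85 ± 0.18, adjusted p = 0.041), and the interneuron calcium-binding protein Calb2 was 1.71-fold lower (-0.78 ± 0.16, adjusted p = 0.041). A second kept probe went the same way without passing for Igsf1 (-1.11, adjusted p = 0.08) and Calb2 (-0.73, adjusted p = 0.12), as it did for Apoc1 (-0.64, adjusted p = 0.093) and Kcnh7 (0.20, adjusted p = 0.61), named below.

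In frontal cortex 36 probes differed, 22 higher and 14 lower in females. Cryba2 (0.49) and Kcnh7, a potassium channel (0.48), were also higher. Also lower were the membrane protein Emp1 (-0.70), the galectin Lgals3 (-0.85), the apolipoprotein Apoc1 (-0.82), Lbhd2 (-0.87), Grb7 (-0.60), Tppp3 (-0.53), Popdc3 (-0.44) and 4930523C07Rik (-0.38). These and the genes above make 18 by their brightest probe, and 8 more genes passed by a dimmer probe alone. For 3 of them the brightest probe was near 0 or of opposite sign, namely Celf2 (0.81, adjusted p = 0.038, brightest 0.03), Foxk2 (0.67, adjusted p = 0.0083, brightest 0.02) and Ints3 (0.56, adjusted p = 0.041, brightest -0.16). For the others it had the same sign without passing, namely Frmd4a (0.68, adjusted p = 0.033, brightest 0.42), R3hdm1 (0.68, adjusted p = 0.03, brightest 0.27), Rspo2 (0.41, adjusted p = 0.027, brightest 0.26), Itih3 (-0.59, adjusted p = 0.007, brightest -0.42) and Rimkla (-0.39, adjusted p = 0.035, brightest -0.19). The median of all probes was close to 0 in this comparison, and with median scaling in place of quantile normalization the split was 23 higher and 6 lower. Xist, Eif2s3x, Emp1, Cd6, Cryba2 and the dimmer probes of Foxk2 and Itih3 stayed past the threshold with any 1 array left out. Id2 lost its call without male frontal cortex replicate 5 (adjusted p = 0.055). Igsf1 and Lbhd2 lost theirs in 20 of the 24 fits, Lhx8 and Kcnh7 in 19, Calb2 in 18, 4930523C07Rik in 12, Tppp3 in 8, Popdc3 and Tnnc1 in 6, Apoc1 and Grb7 in 5 and Lgals3 in 4. Among the dimmer probes Ints3 lost its call in 14, Celf2 in 11, Frmd4a in 8, R3hdm1 in 7, Rimkla in 6 and Rspo2 in 4. The count itself rested on single arrays. It was 37 higher and 68 lower without male frontal cortex replicate 1, and in total 62 without replicate 2, 16 without replicate 3, 17 without replicate 4 and 12 without replicate 5, and it was 17 without female frontal cortex replicate 1, 3 or 4 and 97 without replicate 5. With the label batch as a block the count was 79, in label batch a alone it was 4 and in label batch b alone 200. A fit to the frontal cortex arrays alone gave 7.

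**Figure D2:**
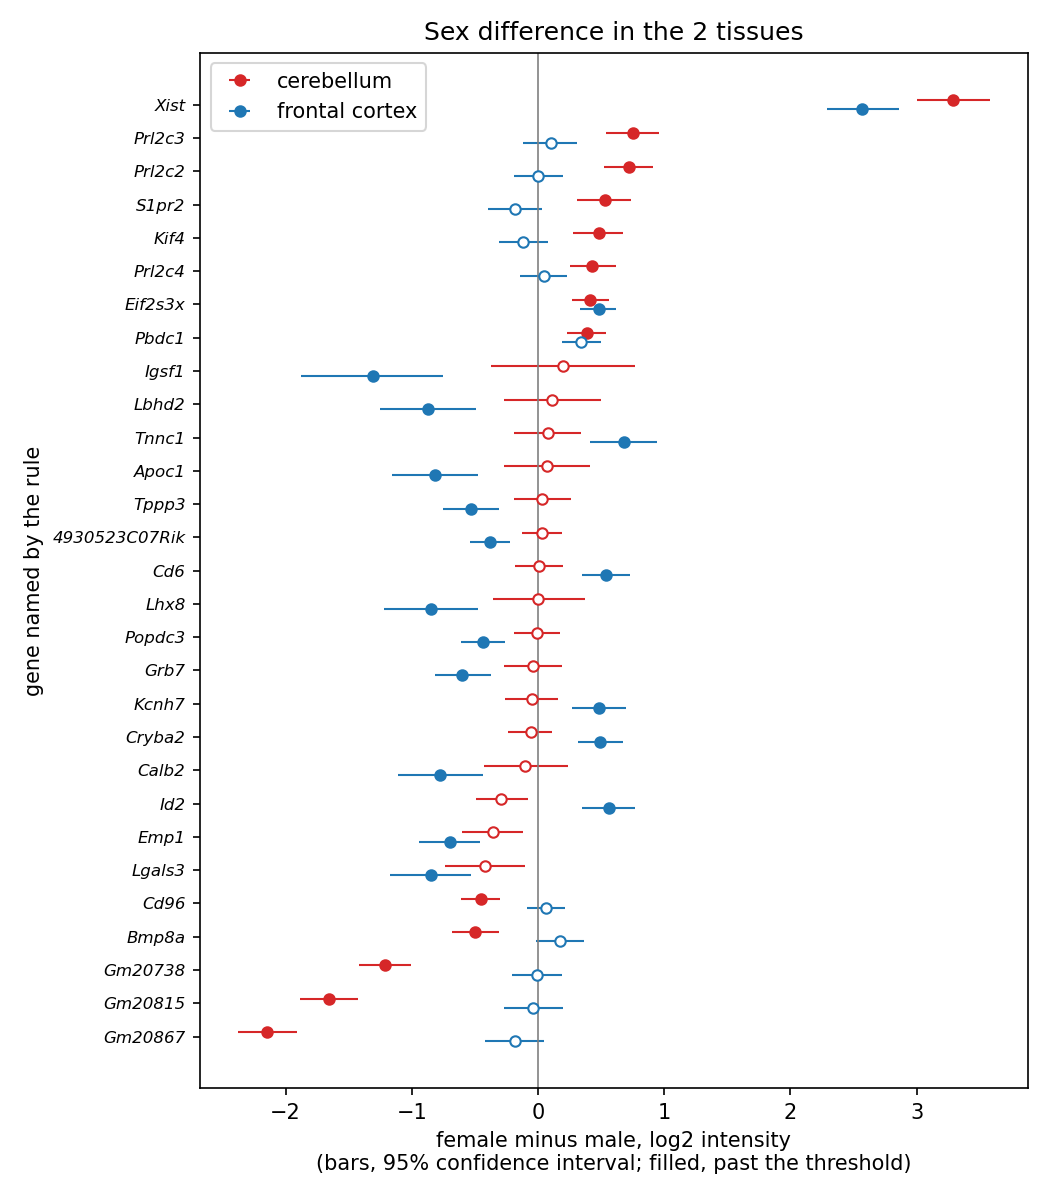
Female minus male difference in log2 intensity (horizontal axis) for each gene named for a sex difference by its brightest probe (vertical axis), in cerebellum and frontal cortex, 6 arrays per group. Bars are 95% confidence intervals and filled points passed the threshold, with Xist at 3.29 in cerebellum and 2.57 in frontal cortex.

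Of the gene lists, X-linked genes known to escape inactivation were higher in female frontal cortex (8 measured, 2 higher and 6 not past the threshold, 4 when adjusted over the list alone, median 0.36, adjusted p = 1.1e-10), and the call held with an estimated correlation (adjusted p = 1.8e-05). Striatal neuron markers had the most negative median (10 measured, 0 past the threshold over all genes, 9 lower when adjusted over the list alone, median -0.67, adjusted p = 3.5e-10, and adjusted p = 0.15 with an estimated correlation). Syndig1l (-0.94), Rgs9 (-0.94), Gpr6 (-0.74) and the dopamine receptor Drd2 (-0.73) were among its members. This list also followed the label batch, a comparison chosen after the data were seen, being higher in batch b by 0.97 in male frontal cortex (adjusted p = 7.8e-15, and 0.039 with an estimated correlation) and by 0.55 in female frontal cortex (1.4e-07 and 0.41), and its median sex difference was -0.30 within batch a and -0.80 within batch b. Olfactory bulb markers (median -0.41, adjusted p = 0.0023, and adjusted p = 0.17 with an estimated correlation) and brainstem and hindbrain genes (-0.39, adjusted p = 0.0046, and adjusted p = 0.15 with an estimated correlation) also shifted lower. So did complement genes (-0.26, adjusted p = 0.0021, and adjusted p = 0.19 with an estimated correlation), myelin genes (-0.14, adjusted p = 0.0013, and adjusted p = 0.38 with an estimated correlation), heat shock genes (-0.16, adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation) and astrocyte markers (-0.11, adjusted p = 0.009, and adjusted p = 0.15 with an estimated correlation). Granule cell markers (-0.07, adjusted p = 0.04, and adjusted p = 0.17 with an estimated correlation) and the Y-linked genes Eif2s3y and Uty (-0.28, adjusted p = 0.02, and adjusted p = 0.15 with an estimated correlation) completed the lower lists. Endothelial markers (0.12, adjusted p = 0.0079, and adjusted p = 0.17 with an estimated correlation) and immediate early genes (0.14, adjusted p = 0.0063, and adjusted p = 0.38 with an estimated correlation) shifted higher. The median sex difference of immediate early genes changed sign between the batches, being -0.32 within batch a and 0.38 within batch b. For complement genes it was 0.02 within batch a and -0.37 within batch b. Of these 12 lists 1 passed with an estimated correlation, and fry passed 5. Of the 12, 8 also differed between the label batches in male frontal cortex by the preset correlation, among them complement genes (0.42, adjusted p = 6.7e-05, and 0.079 with an estimated correlation), and 3 of these in female frontal cortex. In label batch a alone 5 lists passed in place of 12.

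The interaction of sex and tissue tested whether a sex difference in the cerebellum exceeded that in frontal cortex. S1pr2 had an interaction of 0.71 ± 0.15 SE (n = 6 per group, adjusted p = 0.049), being higher in female than male cerebellum and not detectably different in frontal cortex (-0.18, adjusted p = 0.66). Prl2c2 had an interaction of 0.71 ± 0.13 (adjusted p = 0.019) and Gipc2, a PDZ domain protein, one of 0.56 ± 0.11 (adjusted p = 0.044). Id2 went the other way (-0.84 ± 0.14, adjusted p = 0.0049), higher in females in frontal cortex and not past the threshold in the cerebellum (-0.29, adjusted p = 0.63). The second probes of Id2 (-0.34, adjusted p = 0.93) and Prl2c2 (-0.02, adjusted p = 0.99) had no interaction past the threshold. For Xist 1 dimmer probe passed (0.85, adjusted p = 0.00021), kept its call with any 1 array left out and was detected on no male array, while the brightest probe (0.71, adjusted p = 0.34) and the other 2 (0.19 and 0.21, adjusted p = 0.97 and 0.95) did not pass. Gm20867 (-1.96), Gm20815 (-1.62), Gm20738 (-1.20), Bmp8a (-0.67) and Cd96 (-0.51) had negative interactions, since their male excess lay in the cerebellum.

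In total 23 probes had an interaction, 4 positive and 19 negative, of which 20 also differed by sex in the cerebellum and 2 in frontal cortex. With median scaling the split was 1 positive and 18 negative, and without background correction 2 and 14. The animal as a fixed block gave 17 probes, label batch a alone gave 3 and label batch b alone 71. The interaction of S1pr2 lost its call in 20 of the 24 fits with 1 array left out (highest adjusted p = 0.13), and it had adjusted p = 0.051 with the label batch as a block and 0.18 with the animal as a fixed block. Cd96 lost its call in 20, Gipc2 in 17 and Bmp8a in 11 of them, while Id2, Prl2c2 and the 3 Y-linked genes kept theirs in each of the 24. Of the lists, 7 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.38. Striatal neuron markers (median 0.67, adjusted p = 5.3e-07, and adjusted p = 0.38 with an estimated correlation) and myelin genes (median 0.29, adjusted p = 1.4e-06, and adjusted p = 0.38 with an estimated correlation) had the smallest adjusted p. The count of lists was 4 without male frontal cortex replicate 5, female frontal cortex replicate 4, male cerebellum replicate 6 or female cerebellum replicates 1, 2 or 5, and 2 with the run of columns as a block.

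The aim of the series, transcripts set apart by the female cerebellum, was addressed directly by counting probes higher there than in each of the other 3 groups. There were 7 such probes, for 6 genes. They were Xist, Prl2c3, Prl2c2, S1pr2, Prl2c4 and Eif2s3x. Prl2c2, Prl2c3 and Prl2c4 belong to 1 family, and whether their probes report separate transcripts was not tested. They were dim, being detected on 0, 1 and 0 of 6 female frontal cortex arrays. A dimmer kept probe of Prl2c2 did not differ by sex in the cerebellum (0.03). Female cerebellum exceeded female frontal cortex by 1.61 ± 0.10 SE for S1pr2, 1.33 for Prl2c3, 0.75 for Xist and 0.40 for Eif2s3x (n = 6 and 6, limma adjusted p of 2.5e-13, 1.2e-11, 4.9e-05 and 2.2e-05). The dimmer probe of Xist with an interaction went the same way (0.85, limma adjusted p = 1.1e-09). Its remaining kept probes did not differ detectably between the female tissues (0.17 and 0.23, limma adjusted p = 0.57 and 0.32). Of the 7 probes, 3 also had an interaction past the threshold. S1pr2 was also higher in male cerebellum than in male frontal cortex (0.90, adjusted p = 2.5e-08), so that its level was raised in the cerebellum of both sexes. The count ranged from 5 to 9 with 1 array left out, and was 2 in label batch a alone and 29 in label batch b alone.

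Averaged over both tissues of each animal, 30 probes differed between 6 females and 6 males, 10 higher and 20 lower in females. Xist (2.93 ± 0.07 SE, adjusted p = 4e-13), Eif2s3x (0.44, adjusted p = 0.00085), Pbdc1 (0.37, adjusted p = 0.0052), Prl2c3 (0.42, adjusted p = 0.037) and Prl2c2 (0.36, adjusted p = 0.015) were higher. Emp1 was lower (-0.53 ± 0.08, adjusted p = 0.0095), as were Gm20738 (-0.61), Gm20815 (-0.85) and Gm20867 (-1.17). The averages of Prl2c3, Prl2c2 and these Y-linked genes rested on the cerebellum. In frontal cortex alone none of them passed, with differences of 0.10 for Prl2c3, 0 for Prl2c2, -0.01 for Gm20738, -0.04 for Gm20815 and -0.18 for Gm20867. The X-linked Kdm6a passed by a dimmer probe alone (0.47, adjusted p = 0.043, against 0.39 and adjusted p = 0.058 for the brightest). Prl2c3 lost its call in 20, Prl2c2 in 6 and the dimmer probe of Kdm6a in 18 of the fits with 1 array left out. The count was 10 in label batch a alone, 86 in label batch b alone and 56 with the run of columns as a block. A total of 6 probes differed by sex in both tissues, all with the same sign, where independent lists of these sizes would share 0.056. They stood for 2 named genes, being the kept probes of Xist, Eif2s3x and an unnamed probe. Probes of a single gene are not independent, so the overlap does not show sex differences shared by other genes. The unnamed probe ILMN_2899599 fell by 4.54 in female cerebellum and by 4.22 in female frontal cortex, and was chosen for mention after its values were seen.

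Tissue differences were far larger than sex differences. Pcp2, a Purkinje cell protein, was at least 294-fold higher in female cerebellum than in female frontal cortex and at least 288-fold in males (log2 difference 8.61 ± 0.07 SE in females, n = 6 and 6, adjusted p = 2.1e-33 and 1.9e-33). The hindbrain transcription factor En2, detected on 1 of 6 female and 3 of 6 male frontal cortex arrays, was at least 91.7-fold higher in females and 94.3-fold in males, and the granule cell synaptic organizer Cbln1 was 87.1-fold and 67.4-fold higher. In frontal cortex, the dendritic protein Ddn was higher (fitted log2 difference -6.93 in females and -6.82 in males, and at least 6.80 and 6.75 in size), as was the postsynaptic protein Nrgn (-6.78 and -6.70). Ttr, a transport protein made by the choroid plexus, was higher in cerebellum with wide scatter (6.25 ± 0.82 in females and 4.73 ± 0.82 in males).

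In females 12073 probes differed between the tissues, 6651 higher and 5422 lower in cerebellum, and in males 12261, of which 6550 were higher and 5711 lower. With median scaling the splits were 4914 higher and 6745 lower in females and 5192 and 6690 in males. Both sexes shared 10482 probes past the threshold, of which 99.96% had the same sign. The tissue differences of the sexes correlated at 0.972 across kept probes, which are not independent replicates. In females Atp2a3 (5.22), Ddx49 (5.15), Il20rb (5.14, at least 27.2-fold), Lhx1 (5.03, at least 23.9-fold), Dao (4.99, at least 26.7-fold) and Zfp385c (4.63) were also among the most raised in cerebellum, with adjusted p from 1.8e-26 to 7.6e-21. A second probe of Ddx49, detected on all 24 arrays, went the other way (-0.35 in females and -0.38 in males, adjusted p = 0.0067 and 0.0034). Lamp5 (-6.72), Egr3 (-6.16), Stx1a (-5.98), Ctxn1 (-5.67), Krt12 (-5.49), Sst (-5.47), Pdyn (-5.47) and Enc1 (-5.47) were among the most reduced, where Egr3 and Pdyn were detected on 2 of 6 female cerebellum arrays and were at least 61.4-fold and 37.8-fold lower. Dimmer kept probes showed far less for Egr3 (-0.39 in females and -0.09 in males, limma adjusted p = 0.0047 and 0.53). The same held for Il20rb (0.55 and 0.28, limma adjusted p = 0.00076 and 0.072). Label batch a alone gave 7335 probes in females.

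Cell type lists followed the tissues. Granule cell markers were higher in cerebellum in both sexes (18 measured, 17 higher and 1 lower in each, the same when adjusted over the list alone, medians 2.71 in females and 2.65 in males, camera adjusted p = 1.7e-11 and 1.8e-11). Examples in females were Grm4 (3.95) and Zic2 (4.40). Purkinje cell markers were higher as well (11 measured, 10 higher and 1 lower, medians 2.69 and 2.73, adjusted p = 2.9e-08 and 7.2e-08), including Lhx5 (3.51, at least 7.90-fold) and Pvalb (2.72). Cortical excitatory neuron markers such as Tbr1 (-4.98, at least 27.3-fold) and Camk2a (-4.35) were lower (17 measured, 15 lower and 2 higher, medians -3.64 and -3.19), as were forebrain interneuron markers such as Dlx1 (-4.06, at least 13.7-fold) and Vip (-4.23, at least 14.4-fold), with 12 of 12 lower in each sex. Microglia markers were lower in cerebellum (13 measured, 12 lower, medians -1.18 and -1.37), including Fcrls (-2.56), Aif1 (-1.53) and Cx3cr1 (-1.68). These 5 lists kept their calls with an estimated correlation in both sexes.

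Some lists lost their call by tissue with an estimated correlation. Immediate early genes were lower in cerebellum, with 12 of 15 lower in each sex (medians -1.85 and -1.29, adjusted p = 2.9e-05 and 4e-04, and adjusted p = 0.20 and 0.28 with an estimated correlation), including Egr1 (-2.24), Arc (-2.73) and Junb (-2.40) in females. Astrocyte markers such as Gdf10 (4.61) and Hopx (2.27) were on balance higher, though Slc1a2 was lower (-1.47), with medians of 0.81 and 0.75 (adjusted p = 0.023 and 0.049, and adjusted p = 0.19 and 0.20 with an estimated correlation). Striatal neuron markers were lower (medians -0.84 and -1.43, adjusted p = 0.012 and 0.00027, and adjusted p = 0.54 and 0.35 with an estimated correlation), with 7 of 10 lower in females and 10 of 10 in males. Choroid plexus markers passed in females (10 of 11 higher, median 1.16, adjusted p = 0.027, and adjusted p = 0.59 with an estimated correlation) and had a median of 0.49 in males (3 of 11 higher, adjusted p = 0.22). A difference between the sexes was not shown, as the interaction of this list had adjusted p = 0.00043 with the preset and 0.57 with an estimated correlation. Of the sphingosine-1-phosphate genes, 10 of 17 were higher and 2 lower in cerebellum in each sex, led by the phosphatase Sgpp2 (2.82 in females), and the list itself did not pass (adjusted p = 0.092 and 0.11).

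**Figure D3:**
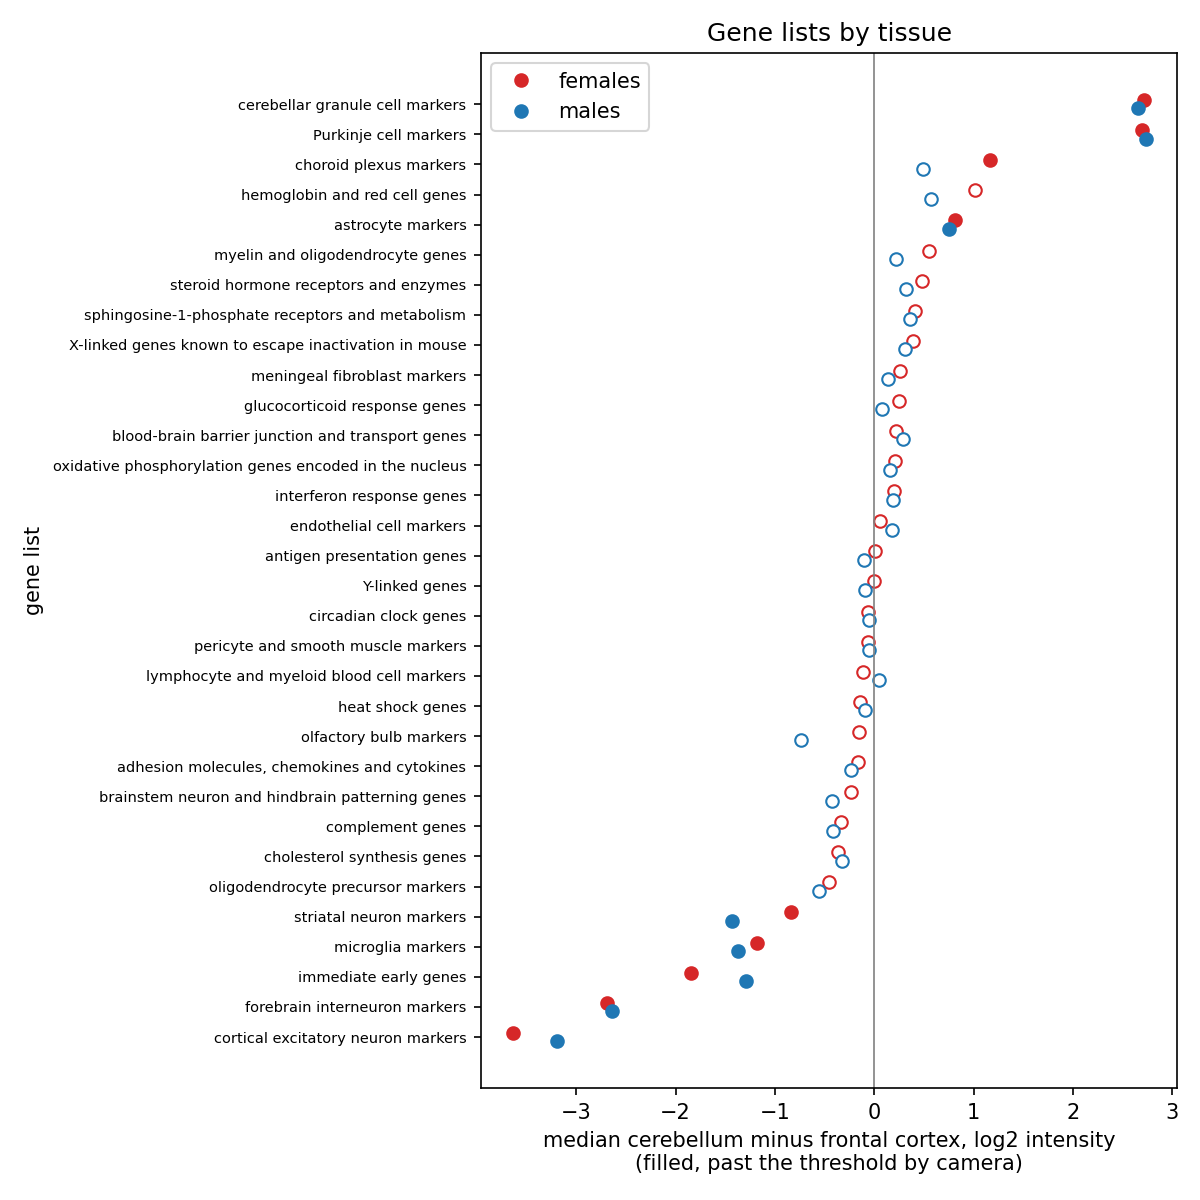
Median cerebellum minus frontal cortex difference of each gene list in log2 intensity (horizontal axis), by list (vertical axis), in females and males, 6 arrays per group. Filled points passed the threshold by camera with its preset correlation, and the granule cell medians were 2.71 in females and 2.65 in males.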

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

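The tests that weigh explanations of S1pr2, of Lcn2 and of the probes of the male cerebellum were chosen after those results were seen, while the interaction, the label batch as a block or alone and the counts of other splits were set out beforehand.

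For the genes named in the report, 64 probes were examined in each of the 4 groups, 53 brightest probes and 11 dimmer ones, and in 13 of 256 groups of 6 arrays 1 array lay far from the others, where chance would give about 1 in 20, or 12.8. Female cerebellum replicate 4 was high for Egr3 (log2 level 6.21, others 4.26 to 4.95), Krt12 (5.49, others up to 4.94) and Sst (7.96, others up to 6.11), 3 genes named in the report for far higher levels in frontal cortex. Female frontal cortex replicate 1 was low for Igsf1 (5.21) and Pdyn (9.37) and high for Prl2c4 (4.62). The others were male cerebellum replicate 3 for Prl2c3 (5.54), male cerebellum replicate 1 for Cbln1 (14.19), male cerebellum replicate 2 for Il20rb (10.36), male frontal cortex replicate 3 for Lhx1 (4.68) and female frontal cortex replicate 6 for Zfp385c (5.75). Among the dimmer probes they were female frontal cortex replicate 5 for Frmd4a (5.97) and male cerebellum replicate 4 for Rspo2 (4.32).

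The sex difference differed between tissues, by the interaction in limma, for 9 genes by their brightest probe and for Xist by a dimmer one. The difference in cerebellum minus that in frontal cortex was 0.71 for Prl2c2, 0.71 for S1pr2, 0.56 for Gipc2, -0.51 for Cd96, -0.67 for Bmp8a, -0.84 for Id2, -1.20 for Gm20738, -1.62 for Gm20815 and -1.96 for Gm20867. It was 0.85 for the dimmer probe of Xist, and 0.71 for its brightest probe, which did not pass (adjusted p = 0.34). It also differed for 7 gene lists by camera with its preset correlation and for 0 with an estimated correlation or by fry. Their median interactions were -0.15 for circadian clock genes, -0.21 for immediate early genes, 0.46 for choroid plexus markers, 0.29 for myelin genes, 0.67 for striatal neuron markers, 0.48 for brainstem and hindbrain genes and 0.56 for olfactory bulb markers.

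S1pr2 was higher in female than in male cerebellum. Against the run of 6 columns as the cause, the difference was 0.51 ± 0.10 (SE) with the run as a block and 0.53 ± 0.10 without. Run by run, with 1 to 3 arrays per sex, it was 0.15, 0.74, 0.61 and 0.23 in runs 1 to 4, so it was uneven between runs. Against RNA of choroid plexus, vessels or meninges, it was 0.50 ± 0.11 with the levels of 4 such marker lists as covariates, where the adjusted p went from 0.023 to 0.059 as the difference shrank slightly and its standard error grew. A factor that goes with the label batch stays open, since within label batch a the difference was 0.13, and the difference between the batches was 0.60 (limma unadjusted p = 0.0049, adjusted p = 0.13). The shift from batch a to b was -0.29 in males and 0.30 in females, and a biological sex difference of the cerebellum stays open as well.

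A set of 17 probes with a sex difference in the cerebellum and an interaction was detected on each male cerebellum array and on at most 3 arrays of each other group, with 0 of 6 male frontal cortex arrays for 11 probes and 1 to 3 for 6. It held the Y-linked Gm20738, Gm20815 and Gm20867, the autosomal Bmp8a and Cd96, and 12 probes without a gene name here, which are not shown to be Y-linked. Testis RNA is argued against by 0 of 14 testis and spermatid genes detected on all 6 male cerebellum arrays and on at most 3 of male frontal cortex. All 17 probes stayed past the threshold in both comparisons with the run as a block. The median male excess was then 1.66 against 1.59 without (median SE 0.10 and 0.11). This outcome was largely fixed by the choice of the set, since the male cerebellum arrays, on each of which its probes were detected, lay in all 4 runs. The block moved these probes by at most 0.09 and other kept probes by up to 0.45. The choice itself leaves little room for the run as the whole cause, and the block adds little to it. The label batch as a block left the median at 1.59 and decides nothing, since each group held the same share of both batches, so a factor that went with the batch in 1 sex alone stays open. Cross-hybridisation to a cerebellar transcript present in both sexes was not decided. The set was picked for a male excess and for detection on at most 3 female cerebellum arrays. Few of its probes could therefore be higher in female cerebellum than in female frontal cortex. Of the 17 probes 2 were, Cd96 (0.31) and an unnamed probe (0.26). What the set has in common stays open, and a sex difference of the cerebellum was not tested apart from it.

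Lcn2, which encodes the iron-binding protein lipocalin 2, was high in both tissues of the 4 males of label batch b. Its lowest level on those 8 arrays was 8.46, against at most 7.21 on the other 16 arrays, and the difference between the batches in males was 4.12 ± 0.35 (SE). This compares 4 males of batch b with 2 of batch a. The SE here and below takes the 2 arrays of an animal as independent, so it may be too small. Handling or hybridisation that differed between the label batches alike in both sexes would raise Lcn2 in females too, where the difference was -1.29 ± 0.35. Handling that went with the batch in males alone stays open. The run of 6 columns is argued against by a difference of 4.11 ± 0.38 with the run as a block. An acute phase response stays open and was not decided, since the lower of the medians over 10 genes of that response was 0.29, below the 0.3 it needed and above the 0.1 that would have argued against it, and a difference in the care of these males was not tested.

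Other splits of the same samples were counted for each result, 100 drawn splits for comparisons of sex and 32 swaps within animals for comparisons of tissue, the real split included. Chance was unlikely as the source of the count in cerebellum, where 3 of 100 splits gave as many probes as the real 33, and the highest others gave 1388 and 128. That count holds the Xist and Y-linked probes, which a true split by sex parts in any case. It therefore does not show that other genes lie beyond chance. Chance could not be excluded for the count in frontal cortex, where 5 of 100 splits gave at least the real 36 and the highest other gave 1223. With 100 drawn splits, 3 and 5 are close, so the tissues are not shown to differ in this. The count does not speak of single genes, since Xist and Eif2s3x had all 6 male frontal cortex arrays below every female array. The splits with 1388 and 1223 probes set runs 1 and 3 of the columns exactly against runs 2 and 4, which points to a structure of the samples that follows the run, and with the run as a block the real counts were 40 and 48. Chance was also unlikely for the counts of the interaction (1 of 100 splits, real 23, highest other 1), the probes highest in female cerebellum (2 of 100, real 7, highest other 17) and the average over tissues (1 of 100, real 30, highest other 5). These counts hold Xist or Y-linked probes too, so the same limit applies to them. For the tissue differences chance could be excluded in females (1 of 32, real 12073, highest other 7702) and in males (1 of 32, real 12261, highest other 8029).

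For the count of gene lists, chance was unlikely by sex in frontal cortex, where 3 of 100 splits gave at least the real 12 and the highest other gave 13. This concerns the preset correlation, and 1 of the 12 lists passed with an estimated one and 5 lists passed by fry. The real count holds the X-linked and the Y-linked list, and 8 of the 12 lists also differed between the label batches in males. The count therefore does not show that any other single list lies beyond chance. Chance could not be excluded for lists by sex in cerebellum (7 of 100, real 7, highest other 10), or for the interaction (8 of 100, real 7, highest other 11). By tissue the swaps decide nothing for lists, because swapping some animals shrinks the tissue difference and leaves the order of genes that camera uses. There 14 of 32 swaps in females (real 9, highest other 13) and 17 of 32 in males (real 8, highest other 12) gave as many lists. The swaps part every pair as the real labels do, and differ in setting tissues of some animals the wrong way round.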

How the results depend on the processing

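Chosen after the data were seen were the run of 6 columns, as a block or alone, and the omission of 2 cerebellum arrays with forebrain transcripts. A lone array of a group in a run was assumed to vary like the others. Of 150 probe counts under an alternative, 99 stayed within 1.5 times the reported count and 51 moved further, and of 55 counts of lists, 42 stayed. Of 5307 values of named genes, 4459 kept direction and side of the threshold, 816 lost their call, 4 gained one and 28 changed sign. The slide was not run because the files do not give it. Except where fewer arrays or probes or a stricter criterion explain a lower count, the cause was not tested.

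The sex difference in frontal cortex counted 22 probes with no filter, 79 with the label batch as a block, 20 with replicate numbers shared between the sexes and 7 from the arrays of that tissue. With detection required on all 24 arrays, which drops sex-specific probes, the counts were 1 by sex in cerebellum, 17 in frontal cortex, 1 for the interaction, 1 highest in female cerebellum and 4 averaged over tissues. Array weights gave 58 in cerebellum, 65 in frontal cortex and 13 highest in female cerebellum. At least 1.5-fold were 21 in frontal cortex, 5651 by tissue in females, 5957 in males, 4 highest in female cerebellum and 16 averaged.

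Label batch a alone gave 16 in cerebellum, 4 in frontal cortex, 3 for the interaction, 7335 by tissue in females, 2 highest in female cerebellum and 10 averaged, with 5 lists in frontal cortex and 2 for the interaction. Label batch b alone gave 149, 200 and 71, with 29 highest in female cerebellum and 86 averaged. The run as a block gave 56 averaged and 2 lists for the interaction. In the order cerebellum, frontal cortex, interaction, tissue in females, tissue in males and highest in female cerebellum, run 1 alone gave 11, 7, 0, 7557, 6888 and 2 and run 3 alone gave 12, 0, 0, 7055, 5448 and 1. Run 2 alone gave 13, 4 and 0, 6500 by tissue in females and 3 highest, and run 4 alone gave 4 in frontal cortex, 1 for the interaction, 7136 and 7141 by tissue and 13 highest.

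Lists with an estimated correlation numbered 1 and 1 by sex, 0 for the interaction, and 5 and 5 by tissue, and by fry 1, 5, 0, 25 and 23.

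With 1 array left out, counts ran from 26 to 38 by sex in cerebellum, 12 to 1.1e+02 in frontal cortex (37 higher and 68 lower at the most), 18 to 24 for the interaction, 11573 to 12229 and 11859 to 12327 by tissue in females and males, 5 to 9 highest in female cerebellum and 23 to 34 averaged. Lists ran from 4 to 7, 10 to 14 and 4 to 9 by sex and interaction, and 8 to 12 and 7 to 9 by tissue.

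Sign changes fell mostly on values near 0. Uty in cerebellum was -0.02 with array weights, 0 in label batch b, -0.02 in run 3, -0.01 without the 2 arrays with forebrain transcripts, and -0.02 to 0.05 with 1 array left out (0 without female cerebellum replicate 6). In run 3 Uty was 0.05 in frontal cortex and -0.07 for the interaction. S1pr5 in label batch b was -0.01 in cerebellum, 0.01 in frontal cortex and -0.01 for the interaction, in run 1 -0.06, 0.17 and -0.22, in run 4 -0.03 in cerebellum, and in cerebellum with 1 array left out from 0 to 0.10. The interaction of Eif2s3y was -0.17 in run 1, -0.40 in run 4, -0.01 without the 2 arrays and -0.03 to 0.12 with 1 array left out. The interaction of Eif2s3x was 0.05 in runs 1 and 2. Grb7 was 0.01 in frontal cortex in run 2, the dimmer probe of Frmd4a was -0.02 there in run 1, and the interaction of Prl2c4 was -0.07 in run 4.

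Detection limited what could be seen, since 40% to 44% of probes rose above the negative controls on an array, and a difference of 0.25 was recovered at 3.5% or lower in simulated data.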

Other observations

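All comparisons of the label batches, the 5 gene lists named below and the check on runs of columns were chosen after the data were seen.

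Genes of the glucocorticoid response list, which was fixed before the data were examined and holds Lcn2, were on balance higher in the 4 males of label batch b than in the 2 of label batch a. Plin4 was higher by 1.28 in cerebellum and 2.18 in frontal cortex (limma adjusted p = 0.0064 and 1.4e-05) and Sult1a1 by 1.01 and 1.44 (0.026 and 0.00089). Fkbp5 (0.71 and 0.67) and Tsc22d3 (1.08 and 0.42) passed in the cerebellum and not in frontal cortex (adjusted p = 0.04 and 0.057, and 0.022 and 0.51). Of the 15 members kept besides Lcn2, 12 had a positive difference in each tissue of the males, and 8 passed in cerebellum and 2 in frontal cortex, with medians of 0.43 in cerebellum and 0.33 in frontal cortex, against 0.02 and 0.04 in females. Per1 (-0.04), Zbtb16 (-0.10) and Pdk4 (-0.12) did not rise in male cerebellum. With Lcn2 included, the list passed in males with an estimated correlation (adjusted p = 0.0043 in cerebellum and 0.02 in frontal cortex). In male cerebellum the label batch and the run of columns were confounded within the group, as the 2 arrays of batch a lay in runs 1 and 3 and the 4 of batch b in runs 2 and 4. With the run as a block, which rests on the other groups there, 0 of the 15 members passed in cerebellum and 3 in frontal cortex, though 14 and 12 had a positive difference (medians 0.47 and 0.29) and with an estimated correlation the list passed in cerebellum (adjusted p = 0.0085) and narrowly missed the threshold in frontal cortex (0.05 after rounding). Plin4 then had 1.41 in cerebellum (adjusted p = 0.06) and 2.10 in frontal cortex (0.00051), Sult1a1 0.87 (0.28) and 1.56 (0.0037), Fkbp5 0.64 (0.33) and 0.72 (0.087) and Tsc22d3 0.68 (0.088) and 0.72 (0.023). The calls of these 15 members in male cerebellum are therefore not separated from the run, while Lcn2 kept its call there with the run as a block (3.91, limma adjusted p = 0.046). Outside the list, and picked by their rank after the values were seen, Mfsd2a (1.07 and 0.96, adjusted p = 0.0015 and 0.003) and Timp1 (0.84 and 1.52, adjusted p = 0.029 and 6.3e-05) were higher in both tissues, and Serpina3n in the cerebellum (1.24, adjusted p = 0.0011). With the run as a block Mfsd2a passed in both (adjusted p = 0.047 and 0.00083), Timp1 in frontal cortex (0.13 and 0.00058) and Serpina3n not in the cerebellum (0.06). A stress response of these males was not tested apart from an acute phase response, for which the deciding median was 0.29.

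The label batches differed by 0.72% of the kept probes in male cerebellum (153, 83 higher in b), 0.54% in male frontal cortex, where all but 11 were higher in b, and 0.18% in female cerebellum (39). In female frontal cortex the count was 0 in limma, with 1658 at an unadjusted p under 0.05. With the run of 6 columns as a block the counts were 10 in male cerebellum, 80 in male frontal cortex, 45 in female cerebellum and 0 in female frontal cortex. Choroid plexus markers were lower in label batch b in female cerebellum (median -1.92, adjusted p = 7.4e-29, and 0.0027 with an estimated correlation) and in male cerebellum by the preset correlation (-0.98, adjusted p = 4e-08, and 0.25). Striatal neuron markers were higher in label batch b in male frontal cortex (0.97, adjusted p = 7.8e-15, and 0.039 with an estimated correlation), and endothelial markers were lower there (-0.26, adjusted p = 0.00032, and 0.039). With the run as a block and an estimated correlation neither passed (adjusted p = 0.054, and 0.05 after rounding), with medians of 0.99 and -0.27. In female frontal cortex the striatal median was 0.55 (adjusted p = 1.4e-07, and 0.41 with an estimated correlation). Since the meaning of the label batches is not stated, no cause was assigned.

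Levels of prolactin, growth hormone, oxytocin and Ddn were uneven between arrays, and the source of these transcripts was not tested. Prolactin (Prl) reached log2 levels of 10.61, 10.02, 8.65 and 8.54 on female frontal cortex replicates 5, 6, 1 and 4, and 9.89 on female cerebellum replicate 1, and growth hormone (Gh) reached 8.25 on male frontal cortex replicate 2. Oxytocin (Oxt) was 10.34 on male frontal cortex replicate 3 and at most 6.49 on the other 23 arrays. Ddn, which marks forebrain neurons here by its tissue difference, was 8.06 on male cerebellum replicate 3 and 8.25 on female cerebellum replicate 4, and 12.18 or more on each frontal cortex array.

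The 5 lists were written after members such as Lhx8, Oxt and Prl had been seen to differ, so their medians describe these arrays and no p is given. In frontal cortex the median female minus male difference was -0.85 over 5 basal forebrain and septal cholinergic genes (-0.99 to -0.66 with 1 array left out), -0.86 over 4 hypothalamic neuropeptide genes, and -0.19 over 10 acute phase and reactive glia genes (-0.23 to -0.14). Without male frontal cortex replicate 3, on which Oxt was high, the hypothalamic median was -0.52, and it was -1 without male frontal cortex replicate 1. The pituitary median of 1.53 rested on Prl (2.93), with Gh at 0.14, and ran from 1.08 to 2.07. The median of 3 testis and spermatid genes was -0.03. In the cerebellum the medians were -0.03, 0.07, -0.12, 1.08 and 0.06 in the order cholinergic, hypothalamic, acute phase, pituitary and testis.

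The second principal component of the kept probes, with 4.9% of the variance against 79.5% on the first, lay for 92.7% between the runs of 6 neighbouring columns (permutation p = 1e-04, the smallest that 10000 permutations can give). Each run held all 4 groups, so the runs were not the same split as sex or tissue.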
